A study of Mus musculus with 6 samples.

How the data were processed

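Gene expression was measured on Affymetrix mouse Gene 2.0 ST arrays in tissue cut from mouse embryos at embryonic day 10.5. Per the labels' protocols, unfixed embryos of the C57BL/6 strain were frozen and cryosectioned, the sections were stained, and 2 regions next to the dorsal aorta were taken by laser microdissection, which cuts a chosen area out of a section. The dorsal region lay between the notochord and the aortic roof, and the ventral region lay under the aorta. The regions were chosen by position, and no marker gene is named for the choice. The labels state that both regions came from the same embryos, and number 3 biological replicates per region. Each sample entered with 200 to 1000 pg of RNA, which was copied into cDNA and amplified by single primer isothermal amplification before biotin labelling, per the labels' protocols. How many embryos or sections entered a sample is not given in the sources used here.

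The deposited values are on a log2 scale, 1 value per probe set and array. Affymetrix Expression Console and RMA are named without versions, per the submitters' processing notes. RMA corrects background, brings the arrays to a common distribution and summarises the probes of each probe set. The log base was not stated and was taken from the values, which ran from 0.97 to 12.9 with array medians between 3.20 and 3.28. The table held 25429 probe sets, 6 arrays and 0 missing values. A total of 24675 probe sets had exactly 1 gene symbol, 0 had several, and 754 were not listed in the platform annotation and stay unnamed. All 24675 were matched by gene number to the GRCm38.p6 gene table, which was used for symbols and gene classes only. The genome build behind the probe sets is not given in the sources used here, so no coordinates are printed. Each gene had 1 probe set, so no choice among probe sets of a gene was needed. Probe-level values, detection calls and scan dates were not used here.

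Ventral was compared with dorsal tissue in limma 3.58.1 under R 4.3.3, with lmFit and eBayes at default settings on the deposited log2 values of the 24675 genes, without a filter on dim probe sets. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method, and the threshold was an adjusted p of 0.05. Log2 fold changes are ventral minus dorsal. The replicate number entered the model as a block, because the labels say that both regions came from the same embryos and the shared number is the only tie between individual samples. The labels do not state that equal numbers mean the same embryo, so the fit without the block was run beside it. With 3 against 3 arrays an exact permutation test of a single gene cannot give a two-sided p below 0.1, so the gene tests rest on the spread that limma shares across genes. The p-values measure the spread between these samples. The number of arrays limits the precision.

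A total of 37 gene lists was fixed before the data were examined, covering the tissues near the aorta, blood and vessel cells, signalling pathways, Hox genes, cell cycle, stress and RNA quality. The 36 lists with at least 5 measured members were tested with camera at a preset inter-gene correlation of 0.01, which compares a list with the other genes. Camera with a correlation estimated per list and fry, which asks whether the members move one way on balance, were run beside it. The list of mitochondrially encoded transcripts had 0 measured members and was not tested. Each list's median log2 fold change was also placed among 10000 random lists of the same size matched on mean expression.

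The genes named were set by a rule fixed at the same point. In each direction 10 genes are named. Those past the threshold would come first by size of change, and open places are filled by the smallest unadjusted p among genes that moved the same way in all 3 pairs of equal number. Predicted genes, olfactory and vomeronasal receptor genes, microRNA genes and other small RNA genes were counted and not named. For each list up to 4 members past the threshold, or up to 2 with the smallest unadjusted p where none passed, are named. Bmp4, Shh, Runx1, Kitl, Pax1, Foxf1, Gata4, Wt1, Gata2 and Noto are named whatever their values.

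The procedure was tested on simulated data for the ventral against dorsal comparison, with 500 changed genes per fold size over 10 repeats. The 24675 genes were drawn independently of each other at the real means, without differences between pairs. Each gene had 1 spread for both groups, pooled from the real arrays and moderated across genes. With the block, the gene test recovered 17.8% of 2-fold, 93.8% of 4-fold and 99.2% of 8-fold changes, and 163 of its 1714 calls were false. Without the block it recovered 39.4% of 2-fold changes, and 95 of 1759 calls were false. The list test recovered a shift of 0.5 log2, the same for every member, in the cell cycle list in 10 of 10 repeats and called 1 of 350 other lists. The real arrays differ from these settings, so the recovered shares may be too high for them. The real ratio of median SDs, dorsal over ventral, was 1.44, and the real changes of the cell cycle members had an SD of 0.96. In the real data 65 genes had an absolute log2 fold change of at least 2, and none passed the threshold. The alternatives were no block, each pair and each single array left out, other thresholds, moderation with trend and robust settings, array weights, cyclic loess, centring of each array on its median, 2 filters on dim genes, every probe set, and other list tests. Restriction to protein-coding genes and the cell cycle list without Pcna were added after the data had been seen. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.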

Results

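Transcript levels next to the dorsal aorta were measured in mouse embryos at embryonic day 10.5, in 3 arrays of laser-microdissected dorsal tissue and 3 arrays of ventral tissue. The series concerns the tissue beneath the aorta as a niche of the first haematopoietic stem cells, and the comparison asks which transcripts distinguish the ventral from the dorsal side. Values are RMA signals on the log2 scale. The array medians lay between 3.20 and 3.28, and 81.4% of the 24675 genes had a mean below 4. In each array between 1235 and 1341 genes exceeded a log2 signal of 5. The brightest transcripts included Mif, a cytokine-like tautomerase, at a mean of 12.2 over the 6 arrays, Snrpe, a core protein of the spliceosome, at 11.2, and Tuba1a, an alpha tubulin, at 10.9, all 3 picked after their values were seen.

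Ventral arrays resembled each other more than dorsal arrays did. Across genes, Pearson correlations between ventral arrays ranged from 0.887 to 0.898, those between dorsal arrays from 0.813 to 0.828, and those between a dorsal and a ventral array from 0.818 to 0.853. Genes are not independent replicates, so these values describe the arrays only. The median standard deviation of a gene was 0.26 over the dorsal and 0.18 over the ventral arrays. The first principal component held 29% of the variance, with the ventral arrays at 25.6 to 33.5 and the dorsal arrays at -44.4 to -13.7.

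**Figure D1:**
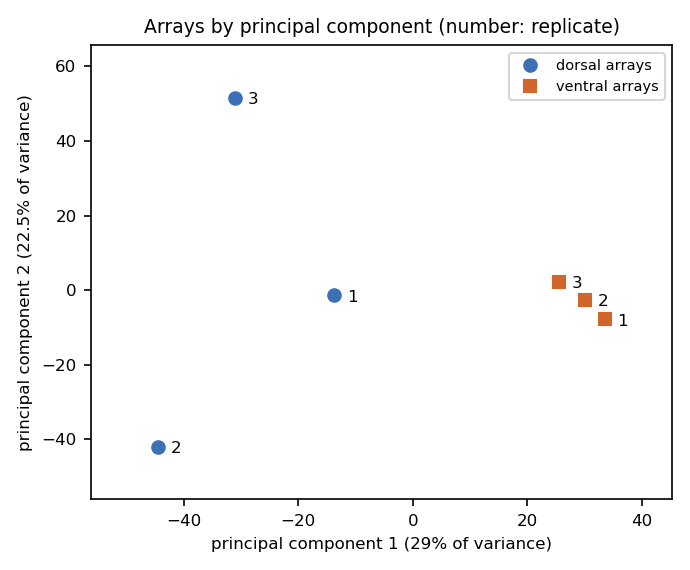
Scores of the 6 arrays on the first and second principal components over all genes tested, which hold 29% and 22.5% of the variance; circles are dorsal and squares ventral arrays, and numbers give the replicate. The ventral arrays lie together at 25.6 to 33.5 on the first component, and the dorsal arrays spread from -44.4 to -13.7 on the first and from -42.0 to 51.6 on the second.

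No single gene separated ventral from dorsal tissue past the threshold. Outside the classes not named, the dorsal-higher gene with the smallest p was Hspb11, also known as Ift25, a subunit of the intraflagellar transport machinery of cilia. Hspb11 was at 5.77 ± 0.09 in dorsal and 2.99 ± 0.23 in ventral tissue (SD, n = 3 each), a log2 fold change of -2.77 ± 0.19 (SE). Its ventral mean lay below the array medians and was not shown to be above background, so the difference in transcript level can be larger than this value. Among the genes named it was followed by Ndufa12, a subunit of respiratory complex I, with levels of 10.9 ± 1.68 and 7.91 ± 2.08. This was a 7.99-fold higher dorsal level, with an SE of 0.33 on the log2 scale. The groups overlapped, with dorsal array 2 at 8.98 and ventral array 3 at 9.71. In limma the unadjusted p of Ndufa12 rose from 0.00012 to 0.0314 without the block, so its rank rests on the uncertain pairing. Again outside the classes not named, the ventral-higher gene with the smallest p was Traj50, a joining segment of the T-cell receptor alpha locus. Traj50 was at 5.04 ± 0.32 in dorsal and 7.02 ± 0.13 in ventral tissue. Dynlrb1, a light chain of cytoplasmic dynein, had the largest difference among the 10 ventral-higher genes named for their p, 3.12 ± 0.42. Fabp7, a fatty acid binding protein of radial glia, differed by 1.72 ± 0.21.

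The other ventral-higher genes named were Zfp748, a zinc finger protein (log2 fold change 1.52), Fthl17e, a ferritin heavy chain-like gene (2.36), Rpsa, a protein of the small ribosomal subunit (1.38), Snrpd1, a core spliceosomal protein (2.13), Cenpk, a kinetochore protein (1.36), Btbd35f5 (2.10) and a variable segment of the immunoglobulin kappa locus (1.57). The other dorsal-higher genes named were Rpp38, a subunit of ribonuclease P (-1.54), the actin-severing factor Cfl2 (-1.43), Mcts2 (-1.51), Sh2d1b2 (-1.67), the splicing factor subunit Sf3b6 (-1.67), Fam204a (-1.45), Cox6a1, a subunit of cytochrome c oxidase (-1.41), and Obox3, a homeobox gene of the oocyte (-1.56). By the rule of selection all 20 moved the same way in the 3 pairs, and their limma adjusted p lay between 0.197 and 0.309. In limma without the block the adjusted p was 0.0103 for Hspb11 and ranged from 0.0854 for Traj50 to 0.432 for Cox6a1 among the others. Between these 20 genes in rank stood 21 ventral-higher and 8 dorsal-higher genes of the classes not named. Traj50, Fthl17e, Btbd35f5, Obox3, the immunoglobulin segment, Rpsa, Mcts2 and Cox6a1 belong to families or have near-identical copies, so their signals are uncertain. V and J segments, the class of Traj50, leaned ventral as a group where their mean was above 3, a limit set after the data had been seen (median 0.20).

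Limma called 0 of 24675 genes at an adjusted p of 0.05, and the lowest adjusted p was 0.197. Without the replicate block it called 1 gene, Hspb11, with an adjusted p of 0.0103. At an unadjusted p under 0.05 there were 2522 genes with the block, where 1234 would be expected by chance, and 2765 without it. Of the 2522 genes, 1065 were higher in ventral and 1457 in dorsal tissue, a ventral share of 42.2%, which became 52.7% after cyclic loess and 53.5% after centring each array on its median. The groups did not overlap in 18.7% of genes, where chance gives 10%, with 1663 genes higher in all ventral and 2957 higher in all dorsal arrays. Leaving out both arrays of one number gave 5 genes without number 1, 0 without number 2 and 2 without number 3, and leaving out single arrays in fits without the block gave 0 to 3.

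**Figure D2:**
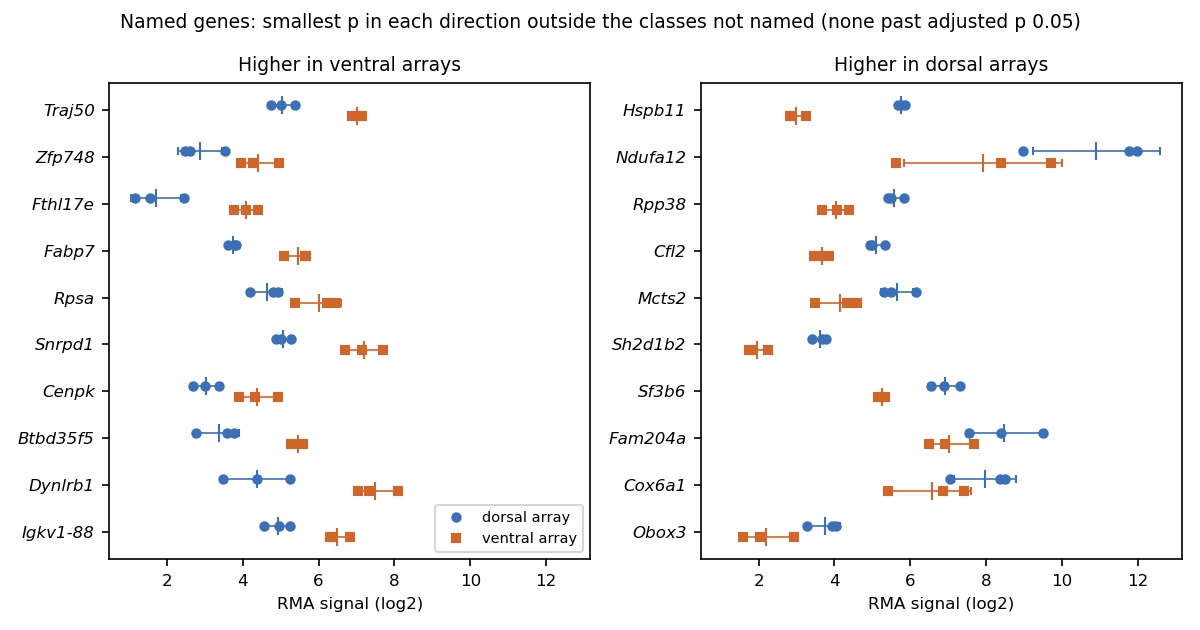
RMA signal (log2) of the 10 ventral-higher and 10 dorsal-higher genes with the smallest p outside the classes not named (predicted, receptor, microRNA and other small RNA genes), 1 point per array, with circles for dorsal and squares for ventral arrays; vertical ticks and bars give the mean and SD of each group. Hspb11 lies at 5.77 ± 0.09 in dorsal and 2.99 ± 0.23 in ventral arrays, and none of the 20 genes passed the adjusted threshold.

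Of the 10 genes followed whatever their values, none passed the threshold, and the 95% interval of each difference included 0. Bmp4, a ligand of the BMP pathway, had a log2 fold change of 0.33, with a 95% interval from -0.39 to 1.05, and Gata2, a haematopoietic transcription factor, 0.32 (-0.21 to 0.85). Runx1, the transcription factor required for the emergence of haematopoietic stem cells, had -0.17 (-0.81 to 0.47), and Kitl, the ligand of the Kit receptor, 0.01 (-0.66 to 0.67). For the ventral mesodermal genes the values were -0.40 (-1.05 to 0.26) for Foxf1, -0.06 (-0.77 to 0.65) for Gata4 and -0.01 (-0.46 to 0.44) for Wt1. For the axial genes they were -0.05 (-0.49 to 0.38) for Shh, -0.20 (-0.83 to 0.43) for Noto and -0.02 (-0.79 to 0.75) for the sclerotome gene Pax1. All 10 genes had group means between 3.23 and 4.43, in the lower part of the signal range, and adjusted p between 0.619 and 0.996 in limma.

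By camera at the preset correlation, cell cycle genes leaned ventral as a group, a call that most alternatives did not keep. Of 24 measured members 16 had a positive log2 fold change, the median was 0.26, and camera gave an adjusted p of 0.0288 over the 36 lists. The adjusted p was 0.921 with an estimated correlation, 0.285 with fry and 0.0677 without the replicate block. The estimated correlation was -0.028, below the preset 0.01, and the unadjusted camera p with it was 0.0653. The rise in p therefore did not come from a higher estimated correlation among the members. This version of camera has few degrees of freedom, so its p does not weigh against the list. No member passed the gene test, and 1 passed adjusted over the list alone. This was Mcm3, part of the replicative helicase, at 3.96 ± 0.32 in dorsal and 5.02 ± 0.06 in ventral tissue, with an adjusted p of 0.0413 over the list and 0.373 over all genes. Pcna, the sliding clamp of DNA polymerase, had a log2 fold change of 4.30 ± 1.36 (SE), with 10.3 to 10.6 in the ventral arrays and 9.19, 1.43 and 7.95 in the dorsal arrays. Without Pcna the adjusted p of the list was 0.0840. The medians of the list without Pcna were 4.26, 3.86 and 3.98 in dorsal arrays 1, 2 and 3 and 4.48, 3.90 and 4.11 in the ventral arrays, so the groups overlapped. The corresponding means did not overlap, at 4.33, 4.36 and 4.25 in the dorsal and 4.73, 4.49 and 4.44 in the ventral arrays. The call was lost after cyclic loess (0.187), median centring (0.0504) and both filters on dim genes (0.0796 and 0.190), and without both arrays numbered 1 (0.112). Fits that left out single arrays had no block, and against 0.0677 for all arrays without the block they gave 0.339 without ventral replicate 1, 0.160 without dorsal replicate 3, 0.0424 without dorsal replicate 2 and 0.0126 without ventral replicate 3. Beside this group, olfactory and vomeronasal receptor genes with a mean above 3 had a median log2 fold change of 0.21 and V and J segments of antigen receptor loci 0.20, against 0.22 for the cell cycle list without Pcna, a comparison and a limit chosen after the data had been seen. The other receptor genes had medians of -0.11 (686 genes with means between 2 and 3) and -0.25 (201 dimmer genes).

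Genes of sclerotome and early cartilage, the mesenchyme around the notochord that forms vertebrae, had lower values in ventral tissue without passing the threshold. Of 22 measured members 18 had a negative log2 fold change, the median was -0.24, and the camera adjusted p was 0.0924. Twist1, a transcription factor of mesenchyme, was at 6.52 ± 0.13 in dorsal and 5.12 ± 0.81 in ventral tissue, and Foxc2 at 4.26 ± 0.26 and 3.76 ± 0.12. The list passed when genes with means under the 25th percentile (0.0346) or under the median (0.0155) were left out. With all genes its camera adjusted p was 0.921 with an estimated correlation, which came out at -0.0339, and the unadjusted p was 0.0993. With the few degrees of freedom of that version, this does not weigh against the list. The erythroid list also had a camera adjusted p of 0.0924, with 10 of 16 members positive and a median of 0.13. Adjusted over the list alone, Hbb-bs, an adult beta globin, passed with a log2 fold change of 1.30 ± 0.18 and Slc25a37, the mitochondrial iron importer of red cells, with 1.81 ± 0.32. Neither passed over all genes. Without the block the unadjusted limma p rose from 0.00047 to 0.0366 for Hbb-bs and from 0.0016 to 0.0019 for Slc25a37. The adjustment over the list was not rerun without the block, so the call of Hbb-bs rests on the uncertain pairing. Brighter globins of the list, picked after their values were seen, did not all lean the same way, with -0.56 ± 0.84 for Hbb-bt (9.53 in dorsal and 8.98 in ventral tissue), -0.29 for Hba-x, -0.37 for Hbb-y and 0.38 for Hbb-bh1, and globin copies are nearly identical in sequence. The erythroid list passed without both arrays numbered 1 (0.00318) and, in fits that also had no block (0.172 on all arrays), without dorsal replicate 3 (0.0342) and without ventral replicate 1 (0.0139). On all arrays with the block its adjusted p was 0.921 with an estimated correlation, a version with too few degrees of freedom to weigh against it.

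The remaining 33 lists had camera adjusted p between 0.651 and 0.991, and none of their members passed the gene test over all genes. Their medians are to be read against a median of -0.06 over all genes. Many members lay near or below the array medians and were not shown to be above background. Examples are Pecam1, at 2.98 in dorsal and 2.93 in ventral tissue, and Cd34, at 2.85 and 2.99. A list median near 0 therefore does not show equal levels on both sides. Among tissues on the dorsal side, the notochord list had a median log2 fold change of -0.15 over 15 members, with 0.48 for Cd24a and -0.46 for Col2a1, and the myotome and dermomyotome list -0.18 over 15 members, with -0.53 for Tnnt1 and -0.33 for Actc1. The neural tube list had a median of -0.00 over 17 members, with 0.84 for Nes, an intermediate filament of neural progenitors, and -0.34 for Neurod1. The list of neural crest, sympathetic and sensory neurons had 0.03 over 25 members, with -0.51 for Tfap2a and 0.67 for Gap43, a growth cone protein.

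Among tissues on the ventral side, the splanchnic and lateral plate mesoderm list had a median of 0.03 over 21 members, with -0.71 for Foxf2 and 0.34 for Prrx1. The list of coelomic epithelium, gonad and adrenal had -0.06 over 21 members, with -0.62 for Dlk1 and -0.35 for Nr0b1. The nephric duct and mesonephros list had -0.06 over 17 members, of which Sall1, a transcription factor of kidney progenitors, passed adjusted over the list alone (-0.96 ± 0.19), and Wnt9b had -0.43. The gut endoderm list had -0.03 over 20 members, with 0.55 for Cldn6 and 0.53 for Foxa3. The liver list had -0.06 over 17 members, of which Serpina1b, an alpha-1 antitrypsin gene with near-identical copies, passed adjusted over the list alone (1.48 ± 0.27), and Rbp4 had -0.45. The primordial germ cell list had -0.13 over 15 members, with -0.68 for Ifitm1 and -0.42 for Prdm14.

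Among vessel and blood cells, the pan-endothelial list had a median of -0.05 over 20 members, and Plvap, the diaphragm protein of endothelial fenestrae, was at 3.92 ± 0.31 in dorsal and 2.92 ± 0.14 in ventral tissue, followed by Sox7 with -0.61. The arterial endothelial list had -0.19 over 16 members, with -0.64 for the Notch ligand Dll4 and -0.45 for Nrp1. The list of haematopoietic stem and progenitor cells had -0.10 over 24 members, with -0.45 for Tal1 and -0.59 for Ikzf2. The macrophage and myeloid list had -0.04 over 19 members, with 0.38 for Cx3cr1 and -0.29 for C1qa, the megakaryocyte and platelet list -0.08 over 11, with 0.47 for Mpig6b and -0.24 for Ppbp, and the smooth muscle and pericyte list -0.15 over 20, with 0.54 for Notch3 and -0.37 for Cnn1.

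The list of haematopoietic stem cell niche factors had a median of -0.02 over 32 members. Its members with the smallest p were Ptn, the secreted growth factor pleiotrophin, at 7.48 ± 1.33 in dorsal and 8.83 ± 0.68 in ventral tissue, and Adm, the vasodilator peptide adrenomedullin, at 3.10 ± 0.58 and 4.23 ± 0.29, with adjusted p of 0.427 and 0.437 in limma. Among signalling pathways, BMP ligands, antagonists and targets had a median of 0.08 over 28 members, with -0.65 for Id4 and -0.79 for Fstl1. The hedgehog pathway had -0.09 over 18 members, with -0.51 for Nkx3-2 besides Foxc2, the Wnt pathway -0.02 over 29, with -0.64 for Wif1 and -0.90 for Sp5, and the Notch pathway -0.12 over 22, led by Dlk1 and Dll4. The TGF-beta and activin pathway had 0.04 over 21 members, with -0.66 for Skil and -0.49 for Inhba, and the retinoic acid pathway -0.14 over 17, with -0.48 for Cyp26b1 and 0.46 for Stra6. The FGF pathway had -0.00 over 19 members, with 0.76 for Spry2, a feedback inhibitor of FGF signalling, and -0.99 for Fgf1. The list of axon and vessel guidance cues had -0.08 over 33 members, with -0.48 for Ntn1 and -0.53 for Ntn3, and inflammatory signalling had 0.01 over 22, with -0.50 for Nfkbia and -0.34 for Ifng.

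Hox genes, which mark position along the body axis, had medians of -0.10 over 14 members for paralogues 1 to 5, with -0.62 for Hoxc5 and -0.49 for Hoxb4, of -0.21 over 12 members for paralogues 6 to 9, with -0.70 for Hoxb7 and -0.55 for Hoxc6, and of -0.01 over 12 members for paralogues 10 to 13, with -0.44 for Hoxb13 and -0.36 for Hoxd13. The extracellular matrix list had -0.03 over 45 members, with -0.50 for Ogn and -0.54 for Loxl1. Stress and immediate early genes, which respond to handling, had -0.15 over 20 members, with -0.58 for Jun and -0.85 for Zfp36, and glycolysis and hypoxia genes -0.04 over 19, with -0.90 for Ldha besides Adm. Median, mean and camera direction differed in sign for the lists of neural tube, macrophages, megakaryocytes, gut endoderm, liver, TGF-beta, FGF, niche factors, extracellular matrix, inflammation, Hox paralogues 10 to 13, glycolysis and ribosomal proteins.

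Of the 42 cytosolic ribosomal protein genes listed as a sign of RNA quality, 31 had a probe set, with a median log2 fold change of -0.04. Although these genes are transcribed at high levels in most cells, 9 of the 31 had a mean below the median of all genes, 3.24, and their means ranged from 2.13 to 8.68. Adjusted over the list alone, Rpsa (1.38 ± 0.17) and Rplp0 (-1.31 ± 0.25) passed, in opposite directions, in the fit with the block. Without the block the unadjusted limma p rose from 0.00027 to 0.0032 for Rpsa and from 0.0022 to 0.119 for Rplp0. Rplp0 would thus not pass, and the adjustment over the list was not rerun for Rpsa. Gapdh, a glycolytic gene often used as a reference, had a mean of 2.04, and Actb, which encodes beta actin, was at 5.47 ± 1.35 in dorsal and 3.35 ± 0.30 in ventral tissue, both looked up after the data had been seen. Genes with many near-identical copies are uncertain on these arrays.

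**Figure D3:**
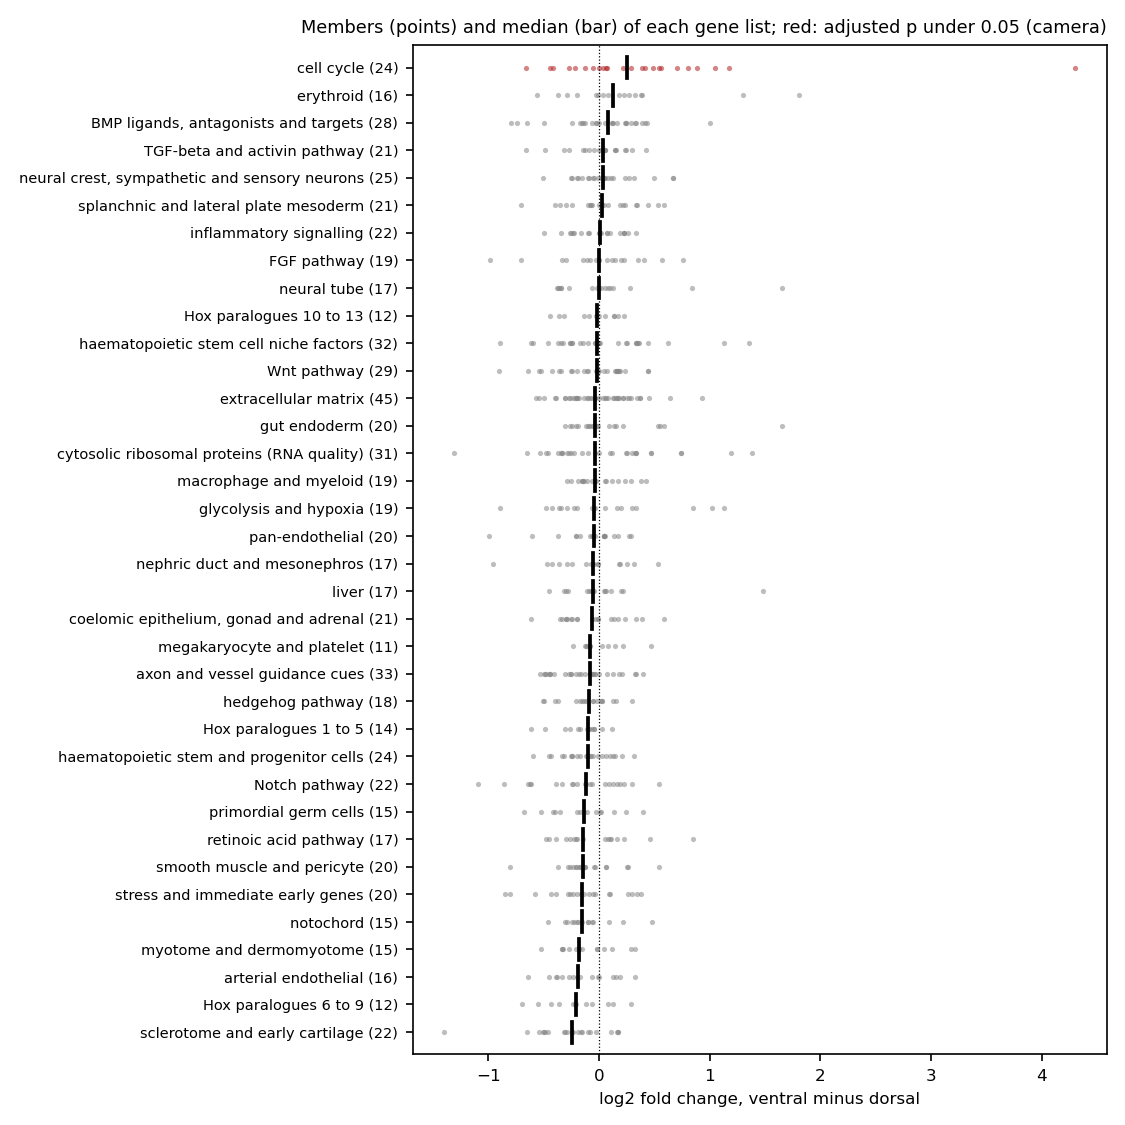
Log2 fold change (ventral minus dorsal) of every measured member of the 36 gene lists, 1 point per gene, with a black bar at the list median and the number of members in parentheses; red marks a camera adjusted p below 0.05. The cell cycle list, with a median of 0.26 and Pcna at 4.30, is the only one in red. Its adjusted p was 0.285 with fry. It was 0.921 with an estimated correlation, a version of camera that can hardly pass any list here. The sclerotome list has the lowest median, -0.24.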

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

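The restriction to protein-coding genes and the cell cycle list without Pcna were chosen after the data had been seen; the other alternatives were planned. The count of 0 genes held with looser and stricter adjusted thresholds, trend and robust moderation, cyclic loess, median centring, both filters on dim genes, every probe set and protein-coding genes only. At an unadjusted p under 0.05 with at least 1.5-fold there were 1596 genes, 723 higher in ventral and 873 in dorsal tissue. Without the replicate block there was 1 gene, higher in dorsal tissue, 0 lists passed, and the cell cycle list had an adjusted p of 0.0677. The block changed no other call over all genes or among the camera lists. Calls adjusted over a list alone were not rerun without it. Without the block the unadjusted limma p was 0.119 for Rplp0, which therefore would not pass over its list, and 0.0366 for Hbb-bs. The deviations of equally numbered arrays from their group means correlated at 0.04, -0.01 and 0.06, none above 0.1, and not every array correlated best with its own number. The labels do not say that equal numbers mean the same embryo, so the pairing stays uncertain, although embryonic globins stood in the order of the numbers in both tissues.

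With arrays left out, between 0 and 5 genes passed, 0 to 5 higher in ventral and 0 to 2 in dorsal tissue, 0 to 1 lists passed, and the cell cycle list ranged from 0.0126 to 0.339. Fits that left out 1 array also had no block, which alone called Hspb11 and lost the cell cycle list, so their changes are not due to the array alone. The genes, named after their values were seen, were Dynlrb1, Gm6158, Hmgb1-ps9, Rab26os and Rny1 without both arrays numbered 1, Mir3064 and Mir350 without those numbered 3, Hspb11, Mir3064 and Scarna9 without dorsal replicate 3, Bex4, Hspb11 and Rny1 without ventral replicate 1, Gm14539, Hspb11 and Ube2s without ventral replicate 2, and Mir350 without ventral replicate 3. No list passed after cyclic loess (cell cycle 0.187), after median centring (0.0504), with an estimated correlation (0.921), with fry (0.285) or with camera on ranks (0.119). The cell cycle list also missed the threshold with means under the 25th percentile (0.0796) or under the median (0.190) left out, where the sclerotome list passed (0.0346 and 0.0155), and without Pcna (0.0840). It passed with trend and robust moderation, every probe set and protein-coding genes. The causes of these changes were not tested. The ventral share at an unadjusted p under 0.05 was 50.9% and 57.7% with the 2 filters on dim genes, against 42.2%.

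Of 1716 values of the 97 named genes under alternatives, 1687 kept direction and side of the threshold, 5 passed only in the alternative, and 24, of 8 genes, changed sign without passing in either; 0 reversed a call. Of 734 values of the other lists, 664 kept both, 5 passed only in the alternative, and 65 changed sign without passing. Array weights came out equal within each blocked pair, so calls kept under them show no stability. The mean of all probe sets of a gene was not run, since each gene had 1. The values hold no background measure, and 81.4% of genes had a mean below 4, so signal over background limits dim genes to an unknown degree.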

Other observations

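Of the tests below, the slope among receptor genes, the list without Pcna and the counts over other splits of the arrays were set before their results were seen, and the others were chosen afterwards. The genes of this paragraph and the next were also picked after their values were seen. Embryonic globins, made by primitive red cells, were among the bright transcripts, and their replicates stood in one order on both sides of the aorta. Hba-x was at 9.41, 9.70 and 11.1 in dorsal arrays 1, 2 and 3 and at 7.08, 10.2 and 12.1 in the ventral arrays. Hbb-y was at 8.48, 8.67 and 10.4 and at 7.07, 8.91 and 10.5, and Hbb-bh1 at 7.78, 7.88 and 10.2 and at 7.03, 8.88 and 11.1. In both tissues the array numbered 3 had the highest and the array numbered 1 the lowest value of each gene, as for Hbb-bs (3.06, 3.42 and 4.80 in dorsal and 4.40, 4.94 and 5.85 in ventral arrays). This shared order goes with a pairing by number, which the correlations over all genes did not show, and globin genes are not independent of each other. Their log2 fold changes were -0.29 for Hba-x, -0.37 for Hbb-y and 0.38 for Hbb-bh1, with limma adjusted p of 0.880, 0.719 and 0.732.

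Several abundant transcripts of growing embryonic cells had nearly equal levels on both sides, with log2 fold changes of -0.06 ± 0.17 (SE) for Mif, -0.05 ± 0.17 for Tuba1a, 0.00 ± 0.17 for the superoxide dismutase Sod1 and 0.06 ± 0.18 for the nucleolar protein Npm1. Mif, at 12.1 to 12.3 in every array, lay near the top of the signal range, where differences can be compressed. The X-linked genes Bex3 and Bex4 leaned ventral, Bex3 from 8.98 ± 0.69 to 10.3 ± 0.28 and Bex4 from 3.20 ± 0.33 to 6.47 ± 2.01, with adjusted p of 0.437 and 0.384 in limma. Bex4 passed the threshold in the fit without ventral replicate 1, its lowest ventral array at 4.16, which also had no block; with all arrays and no block its adjusted p was 0.320. Actb leaned dorsal in all 3 pairs, at 6.98, 5.03 and 4.39 in the dorsal and 3.04, 3.64 and 3.38 in the ventral arrays, with an adjusted p of 0.437.

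Some classes of loci that are not expected to give messenger RNA in this tissue leaned ventral where their signal was above 3. This limit was set after the values were seen, and 686 receptor genes with means between 2 and 3 had a median of -0.11 and 201 dimmer ones -0.25. Among genes with a mean above 3, the median log2 fold change was 0.21 for 478 olfactory and vomeronasal receptor genes, 0.20 for 131 V and J segments of antigen receptor loci, 0.18 for 262 microRNA genes and 0.39 for 58 small nucleolar RNA genes, against -0.02 for 12468 other protein-coding genes. An array-wide intensity trend was present. The slope of the fold change on mean signal was 0.251 among receptor genes (95% bootstrap interval 0.213 to 0.287) and 0.0933 among other genes. Cyclic loess brought these slopes to 0.163 and 0.0200. It left the median of the brighter receptor genes at 0.22 (0.17 to 0.27) and that of V and J segments at 0.21. The trend that loess removed thus did not by itself account for their lean in these arrays. These intervals and the percentiles below come from drawing genes and not arrays, so they leave out the spread between arrays. Receptor medians ran from 3.55 to 3.61 in the dorsal and 3.66 to 3.89 in the ventral arrays. For V and J segments they ran from 3.93 to 4.10 and from 4.11 to 4.29, barely apart. Signal not from mature transcripts, such as genomic DNA, unspliced RNA or non-specific hybridisation, may be stronger in the ventral arrays. MicroRNA and small nucleolar RNA genes may be transcribed in this tissue, so their lean does not bear on this. The V and J segments, whose median lay at percentile 100 of 2000 random lists matched on mean signal, have what it needs. Long non-coding RNA genes (percentile 27.1) did not lean ventral. Pseudogenes leaned dorsal, with a median of -0.05 at percentile 0.25, below the range of -0.03 to 0.05 of 95% of their matched lists. The 3 kinds of signal were not separated from each other, and transcription of these loci in ventral tissue was not tested.

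The cell cycle list was higher in ventral tissue by camera at the preset correlation. With an estimated correlation its adjusted p was 0.921, in a version that can hardly pass any list here. Its median of 0.26 lay at percentile 99.35 of random lists matched on mean signal. The list was looked at because camera called it on the same values, so a high percentile was likely. The percentile therefore cannot decide whether the intensity trend is the whole cause. The sclerotome list lay at percentile 0.34 and the erythroid list at 91.93, inside its random range. Cyclic loess ended the cell cycle call. The list median was 0.26 before and 0.28 after loess (SD over members 0.96 and 0.95). The median of all genes moved from -0.06 to -0.00, and the camera p from 0.0008 to 0.0104, an adjusted p of 0.187. Median centring moved the median of all genes to -0.02 and the camera p only to 0.0014. Why loess ended the call was not tested. Without Pcna the list median was still 0.22 and the unadjusted camera p was 0.00233, so the other members kept a ventral lean. The adjusted p was then 0.0840, past which the call was lost, so a call that rests on Pcna cannot be excluded. The adjusted p of the full list ranged from 0.0126 to 0.921 over its other alternatives. A difference in proliferation stays open on a call that most alternatives did not keep, as does signal not from mature transcripts, which was not tested for this list, whose median without Pcna was 0.22 beside 0.21 for receptor genes above 3.

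Dorsal arrays varied more than ventral arrays, with a ratio of median SDs of 1.44 over all genes. One outlying dorsal array is argued against, since the least different dorsal pair differed 1.37 times as much as the most different ventral pair. Differences between embryos as the cause predicted a higher ratio in bright genes than in receptor genes. The ratio was 1.26 (1.17 to 1.34) in genes with a mean above 5 and 1.51 (1.42 to 1.60) in receptor genes. This comparison cannot decide the question, because signal level was not matched. Of the 1365 receptor genes, 201 had means up to 2 and 686 between 2 and 3. The intervals also come from resampling genes and not arrays. Noise in all probe sets of the dorsal arrays, as from less RNA or uneven amplification, may be involved, since the 1.51 was reached in genes with no known role in this tissue. The RNA amount of each sample was not used here, and a biological part remains open.

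The 6 arrays can be split 3 against 3 in 10 ways, too few for a share under 0.05. The real split gave 0 genes past the threshold, a count that 10 of 10 splits reach by construction, in total and in each direction, so these counts decide nothing. The highest other counts were 7 in total and 6 in each direction, all from splits that part 1 pair and so use the block in another way, and the other splits that part all 3 pairs gave 0. For lists the real count was 1, 2 of 10 splits gave as many, and the highest other gave 2. That other split also parts all 3 pairs, so the call of 1 list does not set the real split apart. Without the block the real split called 0 lists, and some other splits called 1. At an unadjusted p under 0.05 the real split gave 2522 genes, 1 of 10 splits gave as many, namely the real one, and the highest other gave 1576. The 3 other splits that part all pairs of equal number gave at most 768, and without the block the other splits gave 803 to 1109 against 2765.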
